A study of Homo sapiens with 10 samples.

How the data were processed

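Total RNA was measured in 10 human samples, 2 each of foreskin fibroblasts (HFF), lung fibroblasts (HLF), cardiomyocyte-like cells made from them (HFF-CM and HLF-CM) and cardiomyocytes differentiated from the H9 embryonic stem cell line (H9-CM). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was purified with a Qiagen RNeasy Plus Mini kit, amplified and labelled with biotin by NuGEN's Ribo-SPIA chemistry, which copies small RNA amounts linearly, and hybridised to Affymetrix arrays. The array model and the way the fibroblasts were converted are not given in the sources used here.

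The deposited values are log2 expression values, made by the authors with RMA (background correction, quantile normalization and a summary over probes) and Affymetrix Power Tools with genome build hg18, per the submitters' processing notes, which give no versions. Each array had 1 value for each of 25465 Ensembl gene IDs, with none missing and a range from 0.499 to 13.5. How values were combined per gene is not given in the sources used here. For 11317 genes (44.4%) the values had 5 decimals or fewer, while 7331 looked like means of 2 to 3 such values, 4582 of 4 to 7 and 2234 of 8 or more, and 1 gene matched no number of values up to 199. Means over different numbers of values have different spreads, and RMA compresses differences between dim values, so fold changes of dim genes understate the difference. There were no detection calls, so a dim gene could not be told from an absent one, and no array duplicated another, with 6 to 43 of the 25465 values identical in any pair of arrays.

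The values were used as deposited. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on all 10 arrays with 1 mean per kind of cells, followed by Benjamini-Hochberg adjustment over the 25465 genes of each comparison, and genes with an adjusted p below 0.05 were called changed. The fit had 5 residual and 2.66 prior degrees of freedom. The 8 comparisons, their test, 3 correlations of changes and the alternatives were chosen before the data were examined, except as stated next. The noise-corrected positions and distances, the genes 8-fold apart, the overlaps of calls, the separate fits of 4 arrays behind 2 of these overlaps, the comparisons with an H9-CM array left out of the fit, the numerical mixtures of HFF into HLF-CM arrays on the linear scale, and the correlation of the differences by origin were chosen after the data were seen, as were the alternatives restricted to genes with averaged values or to the 6 cardiomyocyte arrays.

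Positions and distances were built from products of differences that use different arrays, so that array noise does not add to them. Positions project the change of the cardiomyocyte-like cells on the difference between their fibroblasts and H9-CM, over all genes. Expected overlaps are those of independent lists in which every gene is equally likely to be called, so genes measured with less noise can raise an overlap above them. The steps were tested on simulated data with the measured means and spreads of 25465 genes, 200 of them changed. With a log2 change of 1, 0% were recovered in each comparison except H9-CM against the mean of fibroblasts (17.5%). With only 200 genes changed, the Benjamini-Hochberg limit was stricter than in comparisons with many changed genes, so recovery there is understated. In the data 5832 genes were called for HFF-CM against HFF, and only 4366 of them changed at least 2-fold. With a log2 change of 2, 68.5% were recovered for HFF-CM against HFF, 67.5% for HFF-CM against H9-CM, 70.0% for HLF-CM against H9-CM and 30.0% for the difference by origin, with at most 9 false calls in any comparison. The simulation gave all kinds of cells the same spread per gene, while replicates of cardiomyocytes varied more than those of fibroblasts. Its false calls therefore do not measure those of comparisons among cardiomyocytes in the data. Simulated positions of 0.5, 0.8 and 1 were estimated at 0.496, 0.795 and 1.00.

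The gene table used here (GRCh38.p14) had 0 entries with an Ensembl ID, so 0 of the 25465 IDs could be matched to a symbol and none of its coordinates was used. The 32 gene lists fixed beforehand, their set test, the named marker genes, and the choice of 1 probe set per gene with 1 symbol were therefore not used. The planned removal of Y-linked genes, XIST and TSIX was not applied either, so these genes are among the 25465 and may add to counts between cells of different donors. The rule for named genes (largest changes among called genes whose groups do not overlap) was limited to 2 IDs per direction, taken from HFF-CM against HFF and followed in HLF-CM against HLF. Alternatives were quantile normalization of the gene values, centring of each array on its median, leaving out dim genes (no compared group reaching the median of all values), limma with trend and robust priors, a fit of only the compared arrays, the replicate number as a block, each replicate left out in turn, and a 2-fold minimum.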

Results

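Gene expression was measured on 10 Affymetrix arrays in 5 kinds of human cells, with 2 samples of each. HFF were fibroblasts of the human foreskin and HLF fibroblasts of the human lung. HFF-CM and HLF-CM were cardiomyocyte-like cells made from each of these fibroblasts, and H9-CM were cardiomyocytes differentiated from H9, an established human embryonic stem cell line. The 3 kinds of cardiomyocytes had been kept for 5 days without glucose and with abundant lactate, a medium meant to remove cells that are not cardiac, so this culture cannot be told apart from the change of cell type in any comparison with fibroblasts. The comparisons address how far fibroblasts of either origin moved toward the H9-CM profile and in which respects the cells differed by origin. The table held 1 log2 value for each of 25465 Ensembl gene IDs on every array, with array medians between 4.63 and 4.72. The labels do not say that the 2 samples of a kind came from separate cultures, so the p-values measure only the spread between these samples, which may be technical, and the small number of arrays limits the precision. Neither the files nor the gene table used here pair the IDs with gene names, so the genes are described as sets, and only 4 IDs are printed.

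The arrays fell into fibroblasts and cardiomyocytes, and among the cardiomyocytes HLF-CM lay close to H9-CM while HFF-CM lay apart. The first principal component took 60.0% of the variance and placed the 4 fibroblast arrays opposite the 6 cardiomyocyte arrays, and the second took 9.53% and placed the 2 HFF-CM arrays away from the rest. Across genes, the arrays of HLF-CM and H9-CM correlated at 0.956 to 0.959, those of HFF-CM and H9-CM at 0.940 to 0.948, and those of HFF-CM and HLF-CM at 0.943 to 0.950. Arrays of 1 kind of cells correlated at 0.963 in HFF-CM, 0.973 in HLF-CM, 0.963 in H9-CM, 0.981 in HFF and 0.984 in HLF. Cardiomyocyte-like cells correlated with their own fibroblasts at 0.871 to 0.881 for HFF and 0.872 to 0.876 for HLF. The interquartile range of the gene values was 3.75 to 3.81 log2 units on fibroblast arrays and 3.38 to 3.55 on cardiomyocyte arrays.

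**Figure D1:**
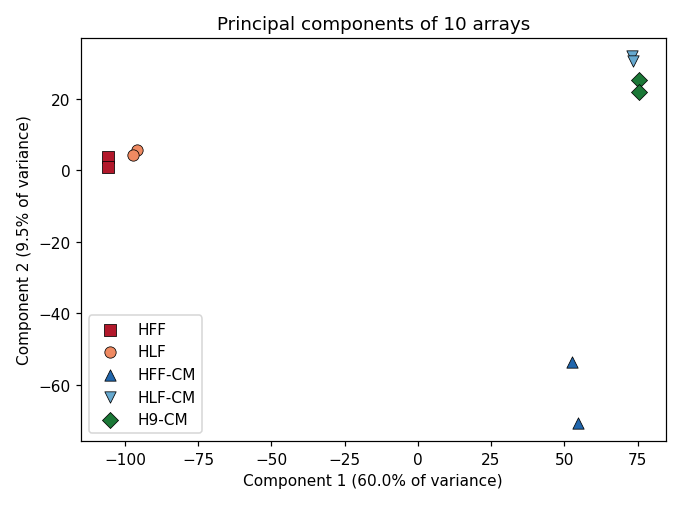
Each point is 1 of the 10 arrays, placed by its score on the first principal component (horizontal, 60.0% of the variance, arbitrary units) and the second (vertical, 9.53%) over 25465 gene values, with colour and shape giving the kind of cells. The 4 fibroblast arrays lie at the left, HLF-CM and H9-CM lie together at the right, and both HFF-CM arrays lie below them.

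The first comparison asked how foreskin fibroblasts differed from the cardiomyocyte-like cells made from them. Of the 25465 genes, 2553 were higher and 3279 lower in HFF-CM, 5832 (22.9%) in all, and 4366 of these changed at least 2-fold. Changes of 16-fold or more were more often rises than falls, with 217 genes up and 109 down. Among called genes whose groups did not overlap, the largest rise was that of ENSG00000106631. Its log2 value went from 2.76 ± 0.59 (SD, n = 2) in HFF to 12.95 ± 0.00 in HFF-CM, next to 12.90 ± 0.05 in H9-CM. ENSG00000198336 rose from 3.40 ± 1.03 to 12.58 ± 0.07, with 12.70 ± 0.00 in H9-CM. Without HFF replicate 2 it rose by 9.90 and ENSG00000106631 by 9.77, so their order is not settled. In cardiomyocytes both lay near the highest values of the arrays, 13.04 to 13.26. Whether saturation hides differences from H9-CM there was not tested. By the same rule ENSG00000204941 had the largest fall, from 9.65 ± 0.07 in HFF to 1.70 ± 0.56 in HFF-CM (2.37 ± 1.52 in H9-CM). ENSG00000221826 fell from 8.84 ± 0.03 to 1.097 ± 0.31 (1.25 ± 0.17 in H9-CM). In limma with Benjamini-Hochberg adjustment the log2 changes were 10.19 (SE 0.26, adjusted p = 8.48e-07), 9.17 (SE 0.42, adjusted p = 7.35e-06), -7.95 (SE 0.61, adjusted p = 8.99e-05) and -7.75 (SE 0.37, adjusted p = 8.79e-06), in the same order. The number of changed genes was 3675 without HFF replicate 1 and 3576 without HFF replicate 2.

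The same comparison was made for lung fibroblasts. HLF-CM had 2570 genes higher and 3128 lower than HLF, 5698 (22.4%) in all, of which 4312 changed at least 2-fold, and 220 rose and 168 fell 16-fold or more. The 4 genes named above moved the same way. ENSG00000106631 rose from 3.07 ± 0.07 (SD, n = 2) in HLF to 12.80 ± 0.01 in HLF-CM, and ENSG00000198336 from 4.12 ± 0.34 to 12.62 ± 0.19. ENSG00000204941 fell from 7.53 ± 0.22 to 2.21 ± 0.18 and ENSG00000221826 from 6.22 ± 0.00 to 1.71 ± 0.88. The limma log2 changes, with Benjamini-Hochberg adjusted p, were 9.73 (SE 0.26, adjusted p = 9.09e-07), 8.50 (SE 0.42, adjusted p = 9.39e-06), -5.32 (SE 0.61, adjusted p = 0.000588) and -4.52 (SE 0.37, adjusted p = 0.000107). The number of changed genes was 3596 without HLF replicate 1 and 3486 without HLF replicate 2.

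The genes that changed in foreskin and in lung fibroblasts were largely shared and moved in 1 direction. Of the 3496 genes called in both origins, 3388 (96.9%) had the same direction, namely 1500 that rose in both and 1888 that fell in both, where independent lists would share 258 and 403. Another 69 genes were higher in HFF-CM than HFF but lower in HLF-CM than HLF, and 39 the reverse, where independent lists would give 314 and 331. Across all genes the log2 changes of the 2 origins correlated at r = 0.71, a description only, since genes are not independent replicates. The 2 comparisons share no array, but the fit over all arrays gives them a common estimate of each gene's spread. With separate fits of 4 arrays each, 1208 genes were higher and 1458 lower in both at an unadjusted limma p under 0.01, where independent lists would share 186 and 298.

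H9-CM differed from the mean of HFF and HLF in 7283 genes, with 3175 higher and 4108 lower, and 4774 of these differed at least 2-fold. The cardiomyocyte-like cells had moved toward this profile from either origin. Among the 2504 genes higher in H9-CM than in HLF, 1492 (59.6%) had risen from HFF to HFF-CM and 37 had fallen, where independent lists would give 251 and 322. Of the 3400 genes lower in H9-CM than in HLF, 2026 (59.6%) had fallen in HFF-CM and 69 had risen, against 438 and 341. Likewise, 1667 of 2810 genes (59.3%) higher in H9-CM than in HFF had risen from HLF to HLF-CM and 2170 of 3619 lower genes (60.0%) had fallen, against 284 and 445 in independent lists. Using the fibroblasts of the other origin keeps the compared changes free of shared arrays. The calls of HFF-CM and HLF-CM against their fibroblasts come from the fit over all arrays, so each gene's estimate of spread is still shared. These overlaps were not repeated with separate fits. Across genes, the change from HFF to HFF-CM correlated with the difference between H9-CM and HLF at r = 0.72, and the change from HLF to HLF-CM with the difference between H9-CM and HFF at r = 0.77.

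**Figure D2:**
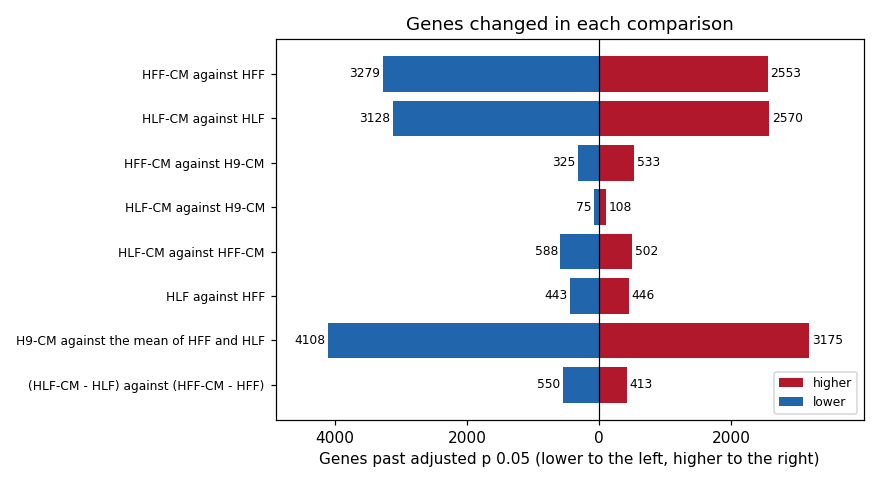
Bars give the number of genes past an adjusted p of 0.05 in limma in each of 8 comparisons (horizontal axis, genes of 25465 tested), with genes higher in the first-named cells to the right and lower ones to the left, and the lowest bar giving genes whose change from fibroblast to cardiomyocyte-like cell differed by origin. Cardiomyocytes against fibroblasts gave 5698 to 7283 genes, HFF-CM against H9-CM 858, and HLF-CM against H9-CM 183.

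HFF-CM and H9-CM differed in 858 genes, far fewer than separated either from fibroblasts. HFF-CM were higher in 533 and lower in 325 of them, and 749 differed at least 2-fold. Of the 533 genes higher in HFF-CM, 355 (66.6%) were also higher in fibroblasts than in H9-CM, where independent lists would share 86.0, and of the 325 lower genes 206 (63.4%) were also lower in fibroblasts, against 40.5. Both comparisons use the H9-CM arrays, whose noise favours such sharing, so independent lists are no measure of it. The fibroblasts here are the mean of HFF and HLF, and HFF-CM were made from HFF. A gene that differs between the donor of HFF and H9 can thus count on the fibroblast side, which leaving out an H9-CM array does not remove. With 1 H9-CM array left out of the fit and the fibroblasts compared with that array alone, fibroblasts were at least 2-fold higher in 209 of 349 (59.9%) and 221 of 390 (56.7%) of the higher genes, compared with 13.7% and 13.4% of all genes, and at least 2-fold lower in 29 and 40. Of the lower genes, fibroblasts were at least 2-fold lower in 75 of 152 (49.3%) and 91 of 183 (49.7%), compared with 10.1% and 10.2% of all genes, and at least 2-fold higher in 18 and 18. A fit of only the 4 arrays of HFF-CM and H9-CM called 0 genes in limma, with a lowest Benjamini-Hochberg adjusted p of 0.0537 and 3132 genes at an unadjusted p under 0.05, so the 858 calls rest on the spread estimated over all 10 arrays. That spread includes fibroblast arrays, whose replicates varied less, with a root mean square SD of 0.330 in HFF and 0.312 in HLF, compared with 0.443 in HFF-CM, 0.386 in HLF-CM and 0.447 in H9-CM. A fit of the 6 cardiomyocyte arrays alone called 201 genes, 139 higher and 62 lower in HFF-CM, of which all but 2 were among the 858. The number was 543 without HFF-CM replicate 1, 450 without HFF-CM replicate 2 and 501 without H9-CM replicate 1.

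HLF-CM and H9-CM were closer still, with 183 genes called, 108 higher and 75 lower in HLF-CM (82 and 85 with arrays centred on their median), and 180 of the 183 at least 2-fold apart. Fibroblasts were also higher than H9-CM in 62 of the 108 higher genes (57.4%) and lower in 43 of the 75 lower genes (57.3%), where independent lists would share 17.4 and 9.35, again with the H9-CM arrays in both comparisons. HLF are part of the fibroblast mean, so genes that differ by donor can count here too. Against an H9-CM array left out of the fit, fibroblasts were at least 2-fold higher in 14 of 35 and 16 of 40 higher genes and lower in 7 and 4, and at least 2-fold lower in 6 of 22 and 9 of 20 lower genes and higher in 7 and 4, so a side was not settled for the lower genes. HFF-CM and HLF-CM departed from H9-CM in some of the same genes, 39 higher in both and 18 lower in both, where independent lists would share 2.26 and 0.957, but the H9-CM arrays are common to both. Another 9 genes were higher in HFF-CM and lower in HLF-CM than in H9-CM, against 1.57, and 0 the reverse, against 1.38. The 2 differences from H9-CM correlated across genes at r = 0.396, while 50 simulations of unchanged groups with shared H9-CM arrays gave a mean r of 0.502. The simulated r is fixed by the shared arrays and the equal spreads. Differences between HFF-CM and HLF-CM lower the observed r, so these 2 values cannot be set against each other. The observed covariance was 0.132 and the simulated one 0.0756, a difference of 0.0560. The simulations gave all kinds of cells the same spread per gene, whereas H9-CM replicates varied more than those of fibroblasts. The root mean square SD was 0.447 in H9-CM, compared with 0.330 in HFF and 0.312 in HLF. The simulated covariance therefore understates the noise of the shared H9-CM arrays, and the difference of 0.0560 overstates the covariance beyond it. With a separate H9-CM array for each difference r was 0.0736. A fit of only the 4 arrays of HLF-CM and H9-CM called 0 genes in limma, with a lowest Benjamini-Hochberg adjusted p of 0.258 and 2735 genes at an unadjusted p under 0.05, and the 6 cardiomyocyte arrays alone also gave 0. Without HLF-CM replicate 1 or 2 the number was 14 or 23, without H9-CM replicate 1 or 2 it was 57 or 60, and without dim genes it was 391, so the size of this set is poorly determined.

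On a scale from 0 at the own fibroblasts to 1 at H9-CM, corrected for array noise, HFF-CM lay at 0.844 (0.844 and 0.845 on the 2 arrays) and HLF-CM at 0.958 (0.957 and 0.959). Both HFF-CM arrays thus lay below both HLF-CM arrays, by more than arrays of 1 kind differed, a spread that leaves out that of the fibroblast and H9-CM arrays entering every position. The root mean square log2 distance to H9-CM, corrected in the same way, was 0.444 for HFF-CM and 0.325 for HLF-CM, compared with 1.14 for HFF and 1.09 for HLF. Genes at least 8-fold higher in the other origin's fibroblasts than in 1 H9-CM array were compared with the other H9-CM array, 430 to 507 genes in each choice. Their median in HFF-CM was 0.69 ± 0.02 (SD, n = 2) log2 units above H9-CM, and in HLF-CM 0.10 ± 0.01. Genes at least 8-fold lower in fibroblasts, 428 to 471 in each choice, had a median of -0.51 ± 0.04 relative to H9-CM in HFF-CM and -0.09 ± 0.03 in HLF-CM.

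**Figure D3:**
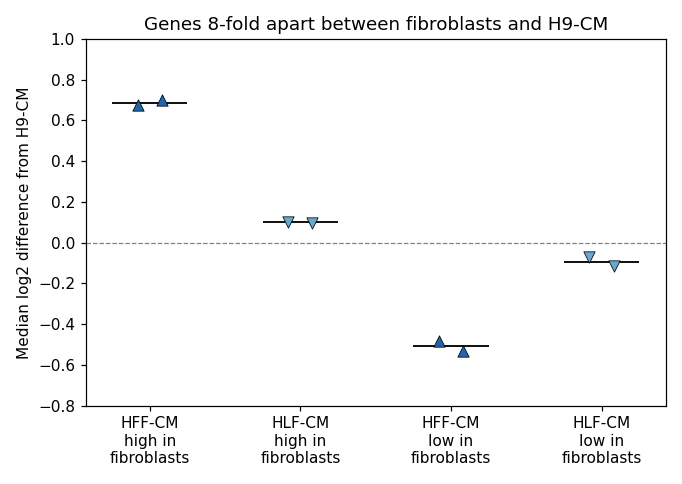
Points give, for each of the 2 arrays of HFF-CM and HLF-CM, the median log2 difference from H9-CM (vertical axis) over genes at least 8-fold higher (left pair) or lower (right pair) in fibroblasts than in H9-CM, and short lines give the mean of the 2 arrays. HFF-CM lie at 0.69 and -0.51 and HLF-CM at 0.10 and -0.09, with the dashed line marking equality with H9-CM.

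HLF-CM and HFF-CM differed from each other in 1090 genes, 502 higher and 588 lower in HLF-CM (785 and 736 without dim genes), with 887 of the 1090 at least 2-fold apart. H9-CM, whose arrays entered the choice of these genes only through the estimate of each gene's spread, lay nearer to HLF-CM in 309 of the 502 (61.6%) and in 429 of the 588 (73.0%). Replicates varied more in HFF-CM than in HLF-CM, with a root mean square SD of 0.443 compared with 0.386. Choosing genes by the difference between the 2 therefore favours noise in HFF-CM, which places H9-CM nearer to HLF-CM. Whether these shares exceed that effect was not tested. Of the 588 genes lower in HLF-CM than in HFF-CM, 328 (55.8%) were lower in H9-CM than in fibroblasts, compared with 16.1% of all genes. Another 104 (17.7%) were higher in H9-CM than in fibroblasts, compared with 12.5% of all genes. Of the 502 genes higher in HLF-CM, 207 (41.2%) were higher and 98 (19.5%) lower in H9-CM than in fibroblasts. A fit of only the 4 arrays concerned called 38 genes, with 3929 at an unadjusted limma p under 0.05, and the 6 cardiomyocyte arrays alone gave 237, with 78 higher and 159 lower in HLF-CM and 228 of them among the 1090. The number was 496 without HFF-CM replicate 2, 352 without HLF-CM replicate 1 and 409 without HLF-CM replicate 2.

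The fibroblasts of the 2 origins differed in 889 genes, 446 higher and 443 lower in HLF, of which 791 differed at least 2-fold. The 446 genes higher in HLF, by a median of 1.55 log2 units, had a median difference of -0.06 between HLF-CM and HFF-CM, and 46.9% of them were higher in HLF-CM than HFF-CM, as were 51.9% of all genes. The 443 genes lower in HLF, with a median of -1.57, had a median of -0.16 between HLF-CM and HFF-CM, and 61.6% were lower in HLF-CM, as were 48.1% of all genes. Across all genes the differences by origin in fibroblasts and in cardiomyocyte-like cells correlated at r = 0.018, and over the 889 genes at r = 0.108. In all, 168 genes were called in both comparisons, where independent lists would share 38.1. Of these, 32 were higher and 62 lower in the lung cells on both occasions, 55 were higher in HLF but lower in HLF-CM, and 19 the reverse. The number of genes separating the fibroblasts was 359 without HFF replicate 1, 286 without HFF replicate 2, 305 without HLF replicate 1 and 247 without HLF replicate 2.

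The change from fibroblast to cardiomyocyte-like cell itself differed by origin in 963 genes, by a test of the difference between the 2 changes in limma. The change was more positive from lung in 413 of them and from foreskin in 550. Among the 963 genes, 125 rose and 192 fell in both origins to different extents, 108 were called in opposite directions, 256 were called only from foreskin and 282 only from lung. The fibroblasts differed in 426 of the 963 genes, the cardiomyocyte-like cells in 498, and both in 84. The number was 386 and 342 without HFF replicate 1 and 2, 348 and 301 without HLF replicate 1 and 2, and 511 and 504 without HLF-CM replicate 1 and 2.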

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

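The tests with the values 0.845, 282 and 0.288 in this part, and the numerical mixtures, were chosen only after the result was seen.

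The change from fibroblast to cardiomyocyte-like cell differed by origin, by the test of that difference, in 963 genes, of which 413 changed more positively from lung and 550 more positively from foreskin. At an unadjusted limma p under 0.05 there were 4407 such genes.

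HFF-CM lay short of H9-CM, at 0.844 of the way from their fibroblasts, while HLF-CM lay at 0.958. A single deviating array is argued against, since the higher HFF-CM array (0.845) lay below the lower HLF-CM array (0.957), and so is the narrower range of the cardiomyocyte arrays, since quantile normalization of the gene values left HFF-CM at 0.840 and the lower HLF-CM array at 0.961. Unconverted fibroblasts with the profile of the HFF arrays are argued against too as the only cause, but only if mixing acts on the deposited values as on RNA. Genes low in fibroblasts called for a fibroblast RNA share of 32.2% and genes high in fibroblasts for only 6.32%. The ratio was 4.87 on 1 HFF-CM array and 5.33 on the other, where a mixture of such fibroblasts with H9-CM-like cells would give the same share. The estimates differed in HLF-CM too (7.36% and 0.746%, with ratios of 6.87 and 13.2 on the 2 arrays, above those of HFF-CM), so a ratio alone does not set HFF-CM apart, but 5% of HFF added numerically to the HLF-CM arrays gave 5.67% from high and only 12.2% from low genes, and 30% gave 31.1% and 35.2%, so none of the 5 shares tried gave both HFF-CM values. The mixtures were made from values after RMA, which compresses differences between dim values. Whether this lowers the share from genes high in fibroblasts, if these are dim in H9-CM, was not tested. Whether fibroblasts left in the lactate culture kept the HFF profile was not measured, so leftover fibroblasts with another profile stay open. Some admixture of fibroblasts beside a further difference stays open, as does the hypothesis that HFF-CM express the H9-CM program less fully. The donor, the tissue of origin and separate preparations of the cells are open and untested, with 1 origin per kind of cells.

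Genes that differed between HLF and HFF differed again between HLF-CM and HFF-CM more often than in independent lists. The 168 shared calls use 1 estimate of spread per gene, so the overlap was repeated with separate fits of 4 arrays each, where 282 genes passed an unadjusted limma p of 0.01 in both, above the upper 95% bound of 132 for independent lists. Of these, 53 were higher and 85 lower in the lung cells both times, 99 were higher in HLF but lower in HLF-CM, and 45 the reverse, so the overlap went in both directions. The bound takes every gene as equally likely to pass. Genes measured with less noise may pass in both fits without a shared difference by origin, so the excess alone does not show one. For the 55 called genes higher in HLF but lower in HLF-CM, expression kept from HFF stays open, since 37 (67.3%) rose from HFF to HFF-CM but choosing genes low in HFF and high in HFF-CM on the same arrays favours such a rise. Whether they are more often fibroblast genes that HFF-CM express could not be settled either, since 52.7% (exact 95% interval 38.8 to 66.3%, which treats genes as independent) were lower in H9-CM than in fibroblasts, compared with 55.8% of all genes lower in HLF-CM than HFF-CM, a ratio of 0.945.

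The cardiomyocyte arrays had a narrower range of gene values than the fibroblast arrays. The mean gap in interquartile range was 0.0803 log2 units for genes with a single value and 0.279 for genes averaged over 2 to 3 values, a ratio of 0.288, with 0.306 for means of 4 to 7 values and 0.0735 for 8 or more. This test fell between its bounds, and the gap did not grow steadily with the number of values averaged. Whether averaging by the authors accounts for any of the gap is therefore not settled, and it cannot be told apart from a difference between the cell types. The lactate culture of all cardiomyocytes is confounded with cell type and no biological explanation was tested.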

How the results depend on the processing

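No printed gene changed direction under any alternative run, and the 4 named genes kept their calls in both origins in all 82 combinations run of gene, comparison and setting. These genes were chosen for the largest changes from HFF to HFF-CM, so this says little about other genes. The alternatives with averaged genes only or cardiomyocyte arrays only, and the positions and the correlation by origin with all their alternatives, were added after the data were seen. Quantile normalization gave 5532 and 5347 genes for HFF-CM and HLF-CM against their fibroblasts, of which 5074 and 5050 were called in the same direction without it, and the share of falls moved from 56.2% to 50.8% and from 54.9% to 51.8%. The balance of higher and lower calls turned from 108 and 75 to 82 and 85 for HLF-CM against H9-CM with arrays centred on their median. Array medians were 4.72 and 4.71 in HLF-CM and 4.65 and 4.63 in H9-CM, so centring lowered every difference between them. For HLF-CM against HFF-CM without dim genes the balance turned from 502 and 588 to 785 and 736, and the cause was not tested. Between HLF and HFF it was near even (446 and 443) and fell on either side across settings. With only the compared arrays, 0 genes were called for HFF-CM against H9-CM, 0 for HLF-CM against H9-CM and 38 for HLF-CM against HFF-CM. The 6 cardiomyocyte arrays gave 201, 0 and 237 in the same order. With their 4 arrays, 4398 genes were called for HFF-CM against HFF, 5334 for HLF-CM against HLF and 748 for HLF against HFF. Fewer arrays and the wider replicate spread of cardiomyocytes were not told apart as causes. HLF-CM against H9-CM gave 391 genes without dim genes, for which the cause was not tested, and 80 with the replicate number as a block. A 2-fold minimum left 4774 genes for H9-CM against fibroblasts. No clear pairing of samples by replicate number was seen, since replicate differences of the groups correlated at -0.0046 to 0.0451. A pairing weaker than the noise of these differences could be missed. The block left the other counts within 1.5 times. Leaving out 1 array, where the lone sample is taken to vary like the others, gave 3576 to 4982 genes for HFF-CM against HFF, 3486 to 4200 for HLF-CM against HLF, 450 to 573 for HFF-CM against H9-CM, 14 to 60 for HLF-CM against H9-CM, 352 to 763 for HLF-CM against HFF-CM, 247 to 359 for HLF against HFF, 5607 to 5971 for H9-CM against fibroblasts and 301 to 773 for the difference by origin. The 3 planned correlations were 0.747, 0.757 and 0.813 without dim genes and 0.758, 0.766 and 0.820 with averaged genes only, for which the cause was not tested, and 0.678 to 0.700, 0.687 to 0.713 and 0.744 to 0.765 with 1 array left out. The correlation by origin ranged from 0.0050 to 0.0284. HFF-CM lay at 0.840 after quantile normalization and 0.842 without dim genes, and HLF-CM at 0.961, 0.961 and, with averaged genes only, 0.970, shifts whose cause was not tested, with 0.844 to 0.845 and 0.957 to 0.959 with 1 array of the placed cells left out, while the fibroblast and H9-CM arrays that set the scale were all kept. The gene list tests with their alternatives and the mean of the probe sets of a gene were not run, since the IDs could not be matched to names and the table held 1 value per gene. Dim genes could not be separated from background, which limits falls to low levels.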

Other observations

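HFF-CM and HLF-CM shared 39 genes higher and 18 genes lower than in H9-CM. Of the 39, 29 were higher and 4 lower in fibroblasts than in H9-CM, and of the 18, 16 were lower and 2 higher, counts in which shared H9-CM arrays and any genes that differ by donor favour the fibroblast side. With genes called without 1 H9-CM array and fibroblasts compared with that array alone, a choice made after the data were seen, fibroblasts were at least 2-fold higher in 12 of 25 and 14 of 29 shared higher genes and lower in 3 and 1. They were at least 2-fold lower in 3 of 11 and 5 of 9 shared lower genes and higher in 3 and 2, too few to settle a side. The sets rest on the spread of all arrays, fibroblasts included, since HLF-CM against H9-CM gave 0 calls with the compared or the cardiomyocyte arrays alone.

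In HFF-CM, 344 genes differed at least 4-fold between the 2 samples, in H9-CM 372 and in HLF-CM 185, compared with 114 in HFF and 92 in HLF. In none of the 5 kinds of cells did these replicate differences follow the difference between H9-CM and fibroblasts, with correlations across all genes from -0.0072 to 0.0223.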
